A study of Rattus norvegicus with 18 samples.

How the data were processed

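RNA from NRK-52E cells, a line of rat kidney proximal tubule epithelium from the Osborne-Mendel strain, was measured on Affymetrix rat expression arrays, on which sets of probes report transcript levels. Confluent cells were exposed to chlorothalonil, an organochlorine fungicide, at 1.1 µM in 0.1% DMSO, or to DMSO alone. Per the labels, that dose is the one that inhibits by 10% at 72 h. RNA was taken at 6, 24 and 72 h, which gives 6 groups of 3 arrays and 18 arrays in all. The arrays were grouped by the treatment, time and replicate number in their titles. The labels call the arrays of a group biological replicates, and the design text speaks of 3 studies per time.

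Per the labels' protocols, total RNA was extracted with Trizol and 6 µg of it was turned into biotin-labelled cRNA. The authors deposited 1 table of log2 expression values for 31099 probe sets, made with GCRMA per the submitters' processing notes. In its standard form, GCRMA subtracts a background modelled from probe sequence, normalizes the arrays to a common distribution of probe values and summarises the probes of each set. Its version and settings are not given in the sources used here. The deposited log2 values run from 0.915 to 16.1, and every sample column was used. The background step leaves transcripts near the detection limit in a narrow band of low values, so fold changes against such a level depend on that step. Normalization to a common distribution would set each array against its own middle and take out a change common to most transcripts. The median of all probe sets lay between 3.93 and 4.22 in the 18 arrays, and between 49.7% and 50.9% of probe sets lay above log2 4.

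The accompanying platform annotation gives 1 gene symbol for 20832 probe sets, several for 436 and none for 9831. Symbols of 20764 probe sets were brought up to date through the Entrez identifier with the RefSeq gene table of assembly GRCr8, which was used for names and for neighbouring genes only. Probe sets with several symbols or none were left out of the gene-level tests. A probe set was kept when its log2 value exceeded 4 in at least 3 of the 18 arrays, which 16686 probe sets did, 12693 of them with 1 symbol. Each gene was represented by its probe set with the highest mean over all arrays, which gave 9149 genes. Of these, 2600 had more than 1 probe set that passed, and 462 were represented by a probe set of a type that can also bind related transcripts. No genome sequence was used.

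Differences were tested with limma 3.58.1 in R 4.3.3. All 18 arrays entered 1 model with a mean for each of the 6 groups, so that every comparison drew on 12 residual degrees of freedom, and the spread of each gene was moderated across genes (2.76 prior degrees of freedom). The comparisons were chlorothalonil against DMSO at each time, an F test over the 3 times together, the difference of the treatment effect between each pair of times, and DMSO at 24 h against 6 h and at 72 h against 24 h. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 9149 genes with a threshold of 0.05. The design text states the treatment comparisons and names no test, so the model was chosen from the group structure. The test, the filter, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined, except that wrong symbol matches of Cdh1 and Nos2 in the lists were removed after values had been seen.

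The rule for named genes took, per treatment comparison, the 10 genes with the highest and the 10 with the lowest log2 change among those called whose treated arrays all lay on 1 side of all DMSO arrays. It took 5 per direction for the other comparisons, the 4 members of each gene list with the smallest p at the time with the most calls in it, and a fixed set of stress-response genes at every time. Genes without a curated name were skipped in favour of the next. A gene whose 3 arrays in a group all lay at or below log2 4 was treated as at background there, and its change is given as a bound, the mean of the brighter group against log2 4. No fold is given where both groups were at background. Of the fixed set, Havcr1, Hmgcs1 and Cyp1a1 were not among the genes tested.

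Of 31 fixed gene lists, 26 had at least 5 tested genes and were tested with camera from limma, which asks whether the genes of a list moved more in 1 direction than the other genes. The correlation between genes was preset at 0.01 and p-values were adjusted over the 26 lists and 3 times together, 78 tests, or over 130 tests for the other comparisons. Alternatives were camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, 1 way and does not compare them with other genes. For the genes of each list, p-values were also adjusted over the list alone. The 5 lists below that size, of fibroblast, endothelial, leukocyte, podocyte and distal nephron markers, are described by their members. Values of spiked control transcripts were compared between treated and DMSO arrays by exact permutation of treatment within each time, with 8000 permutations and 95% intervals.

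The model was tested on independent simulated genes with the DMSO means and spread of the real arrays, 200 of 9149 changed. It recovered 67.6%, 95.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale at 6 h, 61.8%, 90.9% and 100% at 24 h, and 58.8%, 90.9% and 100% at 72 h. Of the calls, 7.41%, 4.00% and 3.49% were false at the 3 times. With the proteasome genes shifted by 0.5 at 24 h, the test called that list and 0 others of the 26. This does not test the preset correlation. The median standard error was 0.0988 for a log2 change and 0.140 for a difference of treatment effects. The number of arrays limits this precision.

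Alternatives tried were quantile normalization of the deposited values, centring of each array on its median, a filter at log2 6, no filter, all probe sets on their own, the second brightest probe set of a gene, a fold change of at least 2, array weights, an intensity trend with robust spread, only the 6 arrays of a time, the replicate number as a block, and leaving out each array in turn. A scaling of each array to the Bacillus subtilis transcripts that are spiked into the RNA as poly-A controls, and list medians with background members at their bound, were added after the data had been seen, as was poly-A scaling with each array left out. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.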

Results

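Expression was measured in 18 cultures of NRK-52E cells, an established line from rat kidney proximal tubule, after chlorothalonil at 1.1 µM or DMSO for 6, 24 or 72 h, with 3 arrays in each of the 6 groups. The question the design poses is what a dose with slight toxicity at 72 h does to transcript levels at each time. Over the 9149 genes tested, replicate arrays of a group were correlated at 0.992 to 0.998. The first principal component held 59.1% of the variance and followed the time of sampling. The second held 12.9% and was higher in the treated arrays at each time. On the first component the treated arrays at 24 h (28.3 to 36.6) lay near the DMSO arrays at 6 h (36.3 to 42.3) and away from the DMSO arrays at 24 h (−33.0 to −27.7). The treated arrays at 72 h (−39.2 to −37.9) likewise lay nearer to the DMSO arrays at 24 h than to those at 72 h (−70.1 to −67.8).

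All changes below are on the deposited scale. When each array was scaled to its spiked poly-A control transcripts instead, an alternative chosen after seeing the data, the median log2 change of all genes moved from −0.0097 to −0.62 at 6 h, from 0.057 to −1.02 at 24 h and from 0.074 to −0.60 at 72 h. The shift comes from the controls, which were brighter in treated arrays by 0.79 on average (exact permutation p = 0.00025, n = 3 per group, the smallest p that 8000 permutations allow). At 24 h they lay at 8.97 in DMSO replicate 1 against 10.1 and 10.3 in the other DMSO arrays, and without that array the median at 24 h was −0.59 instead. Treatment lists whose median turns sign on that scale are named with that value. Beside a list stand camera's adjusted p on the deposited scale and, marked estimated, the same adjusted p with an estimated correlation. Counts adjusted over the list alone are given where they differ. Over all arrays, no list called in the comparisons between times turned sign under poly-A scaling, quantile normalization or centring. A rise or fall at a time is that of treated against DMSO arrays of the same time, whichever had changed since the time before. List medians and changes given after "by" are on the log2 scale.

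At 6 h the treated cells had switched on immediate early and stress genes, while genes of cell division and of cholesterol synthesis were lower than in DMSO. None of these list calls was kept with an estimated correlation (adjusted p = 0.110 for immediate early genes, 0.470 for mitosis and 0.470 for cholesterol synthesis). Atf3, a transcription factor of the stress response, stood at log2 12.36 ± 0.13 against 6.13 ± 0.31 in DMSO (mean ± SD, n = 3), 75.1-fold higher. Hmox1, the heme-degrading enzyme heme oxygenase 1, rose 18.4-fold, and the chemokines Ccl2 and Ccl7 rose at least 16.0-fold and at least 13.9-fold from background. Top2a, the topoisomerase of dividing cells, fell by 1.22 (SE 0.090).

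The strongest group was the immediate early and AP-1 genes, of which 27 of 30 genes rose and 1 fell. Their median rose by 1.46 and stayed above 0, at 0.85, when scaled to the poly-A controls (camera adjusted p = 3.31e-12, or 0.110 estimated). Fos rose 18.5-fold (log2 12.90 ± 0.062 against 8.69 ± 0.093, n = 3), Egr1 12.9-fold and Jun 4.37-fold, all transcription factors induced within minutes to hours of a stimulus. Fosb rose at least 18.8-fold from background. Fosl1 rose 41.4-fold, although in DMSO only 1 of 3 arrays was above background (log2 4.05 ± 1.18).

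Of the heat shock proteins and HSF1 targets, 15 of 20 genes rose and 0 fell, with a median of 0.43 that turned to −0.19 poly-A scaled and was 0.37 with background genes at their bound (adjusted p = 4.43e-06, or 0.286 estimated). Hspa1a, the inducible 70-kDa chaperone, had a log2 level of 4.25 ± 0.64 and rose at least 1.19-fold. Of the ATF4 and amino acid response genes, 17 of 27 genes rose and 1 fell (18 higher and 2 lower adjusted over the list alone), with a median of 0.45, turned to −0.16 poly-A scaled (adjusted p = 1.22e-05, or 0.490 estimated). Ddit3, the stress factor CHOP, rose 3.98-fold. Of the genes of ribosome biogenesis, 16 of 26 genes rose and 1 fell, with a median of 0.52, turned to −0.092 (adjusted p = 0.000277, or 0.404 estimated). On the poly-A scale that median was 0.026 without treated replicate 2 and 0.010 without DMSO replicate 3.

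Smaller shifts passed the test in 5 further lists. In the proteasome 20 of 32 genes rose and 0 fell. The median was 0.18, turned to −0.43 poly-A scaled (adjusted p = 0.000861, or 0.5003 estimated). In oxidative phosphorylation 15 of 41 genes rose and 1 fell (14 higher and 0 lower adjusted over the list alone). The median was 0.13, turned to −0.48 (adjusted p = 0.0315, or 0.751 estimated). In extracellular matrix and mesenchymal genes 14 of 31 genes rose and 4 fell (13 higher and 4 lower adjusted over the list alone). The median was 0.17, turned to −0.45 (adjusted p = 0.0462, or 0.635 estimated). In hypoxia and glycolysis 9 of 28 genes rose and 2 fell (7 higher and 1 lower adjusted over the list alone). The median was 0.14, turned to −0.48 (adjusted p = 0.0438, or 0.684 estimated). In autophagy and lysosome genes 9 of 25 genes rose and 3 fell (9 higher and 2 lower adjusted over the list alone). The median was 0.14, turned to −0.47 (adjusted p = 0.0427, or 0.5003 estimated). All 5 calls were lost on the poly-A scale (adjusted p = 0.173 to 0.351), and the last 4 under quantile normalization (0.116 to 0.429), under centring except hypoxia (0.0557 to 0.0669) and without DMSO replicate 2 at 6 h. That array had the lowest weight of the 18 (0.341) and hybridization controls at 10.4, against 11.7 and 11.6 in the other DMSO arrays of 6 h. Without it oxidative phosphorylation had an adjusted p = 0.0535, extracellular matrix 0.0910, hypoxia 0.0659 and autophagy 0.0523, and 7 lists were called in place of 11. Extracellular matrix was not called with the filter at log2 6 (adjusted p = 0.0559) or without treated replicate 2 at 6 h (adjusted p = 0.0535), treated replicate 1 at 24 h (0.0512) or DMSO replicate 3 at 72 h (0.0501). Hypoxia was not called without treated replicate 3 at 6 h (0.0631), nor autophagy without treated replicate 2 (0.0510) or DMSO replicate 3 (0.0542) at 6 h.

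Lower at 6 h were the genes of mitosis, of which 28 of 30 genes fell and 0 rose. Their median was −0.75 and −1.37 poly-A scaled (adjusted p = 1.74e-09, or 0.470 estimated). Cenpf, a kinetochore protein, fell by 1.44, Bub1b, a spindle checkpoint kinase, by 1.04, Racgap1, a cytokinesis protein, by 0.92 and the proliferation marker Mki67 by 0.84. Of cholesterol synthesis and uptake 15 of 21 genes fell and 1 rose (16 lower and 1 higher adjusted over the list alone). The median was −0.39 and −1.01 poly-A scaled (adjusted p = 0.000861, or 0.470 estimated).

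Outside the lists, Gpr15lg, a secreted ligand of the receptor GPR15, went from background (log2 2.19 ± 0.021) to 8.92 ± 0.21, at least 30.3-fold. Trim72, a membrane repair protein, rose at least 12.1-fold, the histone gene Hist4h4 at least 8.24-fold, the amine oxidase Aoc3 at least 10.6-fold and 1700109H08Rikl at least 11.7-fold. Nod1, a sensor of bacterial cell wall fragments, was at least 4.89-fold lower, and Pdk2, a kinase of pyruvate dehydrogenase, at least 4.52-fold lower. The phosphatase Inpp4a fell by 3.24, the homeobox gene Emx2 by 3.0, the zinc finger genes Zfp469 and Zfp157 by 2.94 and 2.88, and Tbc1d4, a regulator of glucose transporter traffic, by 2.82. Sesn1, of the p53 list, fell by 2.78, the aminopeptidase Enpep by 2.74 and the methyl-CpG protein Mbd5 by 2.69. Of the 3 treated arrays, Inpp4a was above background in 1 and Zfp157, Tbc1d4 and Sesn1 were in 2. The second probe sets of Zfp157, Sesn1 and Pdk2 had log2 changes of −0.87, −0.88 and −0.54.

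Oxidant defence was mixed at 6 h. Of the NRF2 target genes, 13 higher, 9 lower of 27, adjusted p = 0.115, so the list was not called. Osgin1 rose 11.8-fold and Sqstm1, an autophagy receptor, 3.50-fold, and Srxn1 and Slc7a11 rose by 0.91 and 0.91. Txnrd1 rose by 0.57, or −0.048 poly-A scaled (0.061 there without treated replicate 2). By contrast, Nqo1, a quinone reductase, fell by 1.09 (log2 12.20 ± 0.083 against 13.29 ± 0.083, n = 3). Gclm, a subunit of the enzyme that makes a glutathione precursor, fell by 0.35. Of the p53 target genes, 7 higher, 6 lower of 17, 7 and 7 adjusted over the list alone, adjusted p = 0.939. Mdm2 rose by 0.91 and Cdkn1a, a cell cycle inhibitor, by 0.52 (−0.10 poly-A scaled), and Ccng1 had a log2 change of −0.17 (adjusted p = 0.0555). Ccng1 at 6 h was called without treated replicate 3 (adjusted p = 0.0338) or DMSO replicate 2 (0.0454).

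Not called at 6 h were the endoplasmic reticulum unfolded protein response (7 higher, 2 lower of 20, adjusted p = 0.0643), DNA replication (2 higher, 4 lower of 30, 1 and 4 adjusted over the list alone, adjusted p = 0.532), fatty acid synthesis (1 higher, 8 lower of 14, adjusted p = 0.0643) and fatty acid oxidation with PPAR targets (5 higher, 7 lower of 17, adjusted p = 0.774), where Cpt1a fell by 1.28 and Eci1 rose by 1.21. Also not called were epithelial junctions and keratins (4 higher, 1 lower of 8, adjusted p = 0.267), proximal tubule function (2 higher, 0 lower of 6, adjusted p = 0.285), kidney injury markers (5 higher, 2 lower of 11, adjusted p = 0.254), inflammatory and NF-kB target genes (8 higher, 4 lower of 17, 8 and 5 adjusted over the list alone, adjusted p = 0.172) and interferon-stimulated genes (5 higher, 7 lower of 21, adjusted p = 0.654). The same held for AhR targets and xenobiotic metabolism (5 higher, 2 lower of 13, adjusted p = 0.179), metallothioneins and metal transport (2 higher, 4 lower of 12, adjusted p = 0.644), cytosolic ribosomal proteins (1 higher, 0 lower of 25, adjusted p = 0.122) and apoptosis regulators (6 higher, 6 lower of 18, adjusted p = 0.80). Within them the interferon factor Irf1 fell by 1.93, the adhesion receptor Cd44 rose by 0.85, the secreted chaperone Clu rose by 0.55 (−0.070 poly-A scaled, 0.066 there without treated replicate 2), and the caspase gene Casp4 rose by 1.07. Mt1 rose by 1.0 near background, with an adjusted p = 0.0217. The call of Mt1 at 6 h was lost without treated replicate 3 or DMSO replicate 2 or 3 (adjusted p = 0.0792 to 0.131). The unfolded protein response was called without replicate 1 of either group at 6 h (adjusted p = 0.0448 treated, 0.0372 DMSO), and fatty acid synthesis without DMSO replicate 1 (0.0467).

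In all, 5451 of 9149 genes (59.6%) were called at 6 h by limma, 2544 higher and 2907 lower, of which 423 and 627 changed at least 2-fold. Poly-A scaling called 3819, 6.07% of them higher (2275 and 9.45% without treated replicate 2). Of 11 lists called, 0 kept the call with an estimated correlation.

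**Figure D1:**
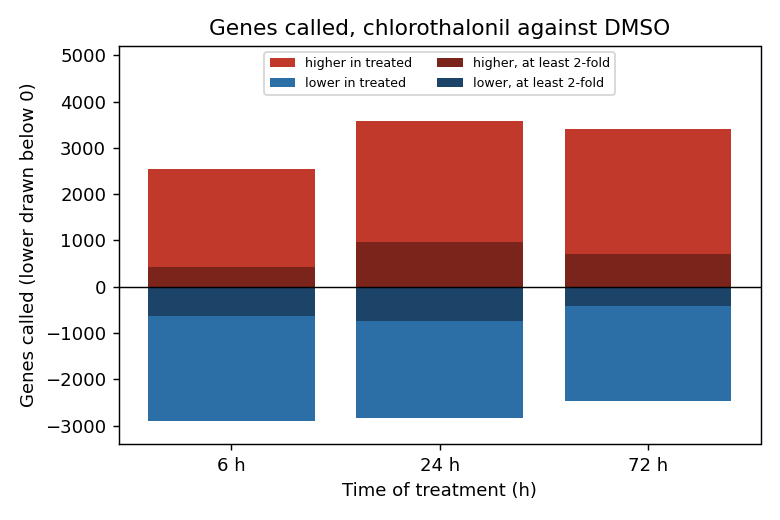
Genes called at each time (h on the x axis), with genes higher in chlorothalonil drawn above 0 and genes lower drawn below 0 on the y axis, and darker bars for changes of at least 2-fold (n = 3 arrays per group). The counts are 2544 higher and 2907 lower at 6 h, 3575 and 2843 at 24 h, and 3408 and 2473 at 72 h, and when scaled to the poly-A controls 6.07%, 3.93% and 8.26% of calls at the 3 times were higher.

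At 24 h chaperones, the proteasome and ribosome biogenesis were higher, and nearly all measured genes of cholesterol and fatty acid synthesis were lower. With an estimated correlation only the call of fatty acid synthesis was kept among these (adjusted p = 0.176 for heat shock genes, 0.215 for the proteasome, 0.110 for ribosome biogenesis, 0.0898 for cholesterol and 0.0170 for fatty acid synthesis). Hspa1a rose from background (log2 2.08 ± 0.048, mean ± SD, n = 3) to 10.32 ± 0.39, at least 80-fold, and Hmox1 rose 45.5-fold (log2 11.01 ± 0.29 against 5.50 ± 0.19). Scd, the desaturase that makes monounsaturated fatty acids, stayed at background in treated arrays, at least 6.15-fold lower than in DMSO, which had gone from log2 2.42 at 6 h to 6.62.

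Of the heat shock proteins and HSF1 targets, 20 of 20 genes rose and 0 fell, and the median of 1.39 stayed above 0 on the poly-A scale at 0.32 or −0.033 there without DMSO replicate 3 (adjusted p = 7.86e-08, or 0.176 estimated). Hsph1 rose 8.0-fold, Hspb1 4.43-fold and Dnajb1 4.12-fold, all cytosolic chaperones or their partners. Of the proteasome genes, 31 of 32 genes rose and 1 fell. The median was 0.81, turned to −0.26 poly-A scaled, or 0.17 there without DMSO replicate 1 (adjusted p = 1.57e-09, or 0.215 estimated). Psmd13, Psmd3 and Psmd8 of the regulatory particle rose by 1.55, 1.54 and 1.37, and Psmd14 by 0.93 (−0.15 poly-A scaled, 0.25 there without DMSO replicate 1). Of ribosome biogenesis 26 of 26 genes rose and 0 fell. The median was 1.45 and 0.37 poly-A scaled (adjusted p = 1.62e-09, or 0.110 estimated). Polr1e, a subunit of RNA polymerase I, rose 4.51-fold, and the nucleolar genes Gnl3, Nop56 and Nop16 rose by 1.70, 1.63 and 1.53.

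Of cholesterol synthesis and uptake 20 of 21 genes fell and 1 rose. The median was −1.79 and −2.86 poly-A scaled (adjusted p = 3.23e-11, or 0.0898 estimated). The cholesterol genes Stard4, Dhcr7, Acat2 and Ebp fell by 2.92, 2.75, 2.36 and 2.10, and Tm7sf2, a sterol reductase, by 4.42. Of fatty acid synthesis 12 of 14 genes fell and 1 rose. The median was −2.23 and −3.30 poly-A scaled (adjusted p = 2.80e-08, or 0.0170 estimated). Acss2, which activates acetate, was 9.68-fold lower, Fads1 8.14-fold lower and Fasn, fatty acid synthase, 5.77-fold lower. In DMSO both lists were higher at 24 h than at 6 or 72 h.

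In the ATF4 and amino acid response 22 of 27 genes rose and 2 fell. The median was 1.05, turned to −0.028 poly-A scaled, or 0.37 there without DMSO replicate 1 and 0.086 without treated replicate 1 (adjusted p = 4.43e-06, or 0.470 estimated). Of the immediate early and AP-1 genes, 24 of 30 genes rose and 1 fell (25 higher and 1 lower adjusted over the list alone). The median was 1.22, 1.09 with background genes at their bound and 0.14 poly-A scaled, or −0.18 there without DMSO replicate 3 (adjusted p = 4.43e-06, or 0.404 estimated). Fosl1 rose at least 29.7-fold and Atf3 41.5-fold. Of the NRF2 target genes, 16 of 27 genes rose and 5 fell. The median was 0.39, turned to −0.68 poly-A scaled (adjusted p = 0.0462, or 0.604 estimated). Srxn1 rose 6.19-fold, the cystine transporter Slc7a11 5.25-fold and Txnrd1 3.03-fold, and Gclm rose by 0.78 (−0.29 poly-A scaled, 0.060 there without DMSO replicate 1), while Nqo1 had a log2 change of 0.0084 (adjusted p = 0.919, and −1.07 poly-A scaled). Without DMSO replicate 2 or 3 at 6 h, treated or DMSO replicate 2 at 24 h, or DMSO replicate 3 at 72 h the NRF2 list had an adjusted p = 0.0535, 0.0504, 0.0546, 0.0516 and 0.0501. In oxidative phosphorylation 23 of 41 genes rose and 2 fell (22 higher and 2 lower adjusted over the list alone). The median was 0.20, turned to −0.87 poly-A scaled (adjusted p = 0.0212, or 0.720 estimated). This call was lost under quantile normalization (adjusted p = 0.116) and poly-A scaling (0.425), and that of NRF2 under quantile normalization (0.0756), the filter at log2 6 (0.0559) and the replicate block (0.0513).

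Lower besides lipid synthesis were mitosis and the unfolded protein response. In mitosis 24 of 30 genes fell and 2 rose. The median was −0.52 and −1.59 poly-A scaled (adjusted p = 2.86e-06, or 0.5003 estimated), with Top2a down by 1.55 and Mki67 by 0.23. Of the unfolded protein response genes, 13 of 20 genes fell and 4 rose (13 lower and 5 higher adjusted over the list alone). The median was −0.33 and −1.41 poly-A scaled (adjusted p = 0.0299, or 0.5003 estimated), and the call was lost there (adjusted p = 0.296). Pdia4 and Pdia6, which form disulfide bonds in secretory proteins, and the regulator Xbp1 fell by 1.27, 0.61 and 0.96, whereas the co-chaperone Dnajb9 rose by 1.34. The call of Mki67 at 24 h was lost without any 1 of the arrays of that time except DMSO replicate 1 (adjusted p = 0.0627 to 0.240).

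Outside the lists, Nppb, the natriuretic peptide B gene, rose at least 83.5-fold, Sprr1a, a cornified envelope protein, at least 49.9-fold, the phospholipase Plcd4 at least 38.2-fold, Serpinb2, a plasminogen activator inhibitor, at least 28.0-fold, Hist4h4 at least 18.6-fold and Sdcbp2 at least 12.5-fold. Ankrd1, a target of mechanical and YAP signalling, rose 66.2-fold. The collagen gene Col8a2 fell by 4.91, Ropn1l by 4.06, Adgrb2 by 4.01, Tmem176b by 4.01, Hacd4 by 3.70 and Pimreg, a mitotic regulator, by 3.70, with Col8a2 and Adgrb2 above background in 1 of 3 treated arrays. Olfml2a was at least 15.7-fold lower and the ferritin receptor Scara5 at least 4.47-fold lower. For Nppb, Plcd4 and Serpinb2 DMSO moved more, from log2 10.18, 7.84 and 6.42 at 6 h to background at 24 h, while treated arrays went from 11.44, 9.25 and 9.19 to 10.38, 9.25 and 8.81. Each of these genes lower at 24 h had risen in DMSO since 6 h, by 2.73 (Pimreg) to 5.83 (Olfml2a).

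The p53 target genes were split at 24 h (10 higher, 7 lower of 17, adjusted p = 0.654). Mdm2 rose 3.06-fold, Plk2 3.43-fold, the exonuclease gene Aen 5.71-fold and Cdkn1a by 0.94 (−0.13 poly-A scaled, 0.28 there without DMSO replicate 1), while Ephx1, an epoxide hydrolase, fell by 2.08 and Ccng1 by 0.28. Hypoxia and glycolysis (8 higher, 12 lower of 28, adjusted p = 0.253) held falls of Aldoc, Pfkfb4, Car9 and Pfkm by 3.52, 2.38, 1.37 and 0.73. Interferon-stimulated genes (7 higher, 8 lower of 21, adjusted p = 0.654) went both ways, with Mx2 and Usp18 up by 3.19 and 2.93 and Stat2 and Psmb9 down by 1.14 and 1.26. AhR targets and xenobiotic metabolism (3 higher, 5 lower of 13, adjusted p = 0.245) showed Mgst2 up by 2.47 and Gstm2 and Gstt2, glutathione transferases, down by 1.69 and 1.44, with Abcg2 at 0.52 (−0.55 poly-A scaled).

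Among metallothioneins and metal transport (3 higher, 5 lower of 12, adjusted p = 0.357), Slc40a1, the iron exporter, and Atp7a, a copper pump, fell by 0.82 and 0.32. The metal-responsive factor Mtf1 and the iron transporter Slc11a2 had changes of 1.09 and −1.23 whose second probe sets read −0.55 and 0.31, so no direction is given for either, and Mt1 rose at least 1.45-fold near background. In epithelial junctions and keratins (2 higher, 4 lower of 8, adjusted p = 0.654), Ocln of tight junctions rose by 1.33, Krt8 by 0.81 (−0.27 poly-A scaled, 0.11 there without DMSO replicate 1), and F11r and Jup fell by 0.86 and 0.48. In cytosolic ribosomal proteins (14 higher, 0 lower of 25, adjusted p = 0.0747), Rpl18, Rpl27 and Rps24 changed by 0.30, 0.19 and 0.18, and by −0.77, −0.89 and −0.90 poly-A scaled, and Rpl28 rose at least 2.09-fold.

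Not called at 24 h were also DNA replication (17 higher, 5 lower of 30, 19 and 5 adjusted over the list alone, adjusted p = 0.115), extracellular matrix and mesenchymal genes (8 higher, 16 lower of 31, adjusted p = 0.0606), fatty acid oxidation with PPAR targets (6 higher, 6 lower of 17, adjusted p = 0.654) and proximal tubule function (2 higher, 3 lower of 6, adjusted p = 0.641). Also without a call were kidney injury markers (2 higher, 3 lower of 11, 2 and 2 adjusted over the list alone, adjusted p = 0.80), inflammatory and NF-kB target genes (8 higher, 4 lower of 17, adjusted p = 0.686), apoptosis regulators (7 higher, 2 lower of 18, adjusted p = 0.306) and autophagy and lysosome genes (13 higher, 5 lower of 25, adjusted p = 0.354). Without 1 array, extracellular matrix genes were called lower (adjusted p = 0.0476 without treated replicate 1 and 0.0462 without DMSO replicate 2 at 24 h), DNA replication higher (0.0485 and 0.0304 without replicate 2, treated and DMSO) and ribosomal proteins higher (0.0470 without treated replicate 3). Median, mean and test, which pointed down, differed in sign for fatty acid oxidation with PPAR targets (median 0.015, mean −0.025), kidney injury markers (0.041, 0.015), epithelial junctions (−0.14, 0.025) and interferon-stimulated genes (−0.23, 0.13).

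At 24 h limma called 6418 of 9149 genes (70.1%), 3575 higher and 2843 lower, with 968 and 741 changed at least 2-fold. Poly-A scaling called 6519, 3.93% of them higher (5592 and 12.2% without DMSO replicate 1, 7641 and 2.17% without replicate 3). Of 11 lists called, 1, fatty acid synthesis, kept its call with an estimated correlation. The 3′ minus 5′ signal of the actin control, a measure of RNA integrity, was lower in all treated arrays of 24 h (1.03 to 1.16) than in all DMSO arrays (1.23 to 1.32, exact permutation p = 0.10, the smallest for 3 against 3).

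**Figure D2:**
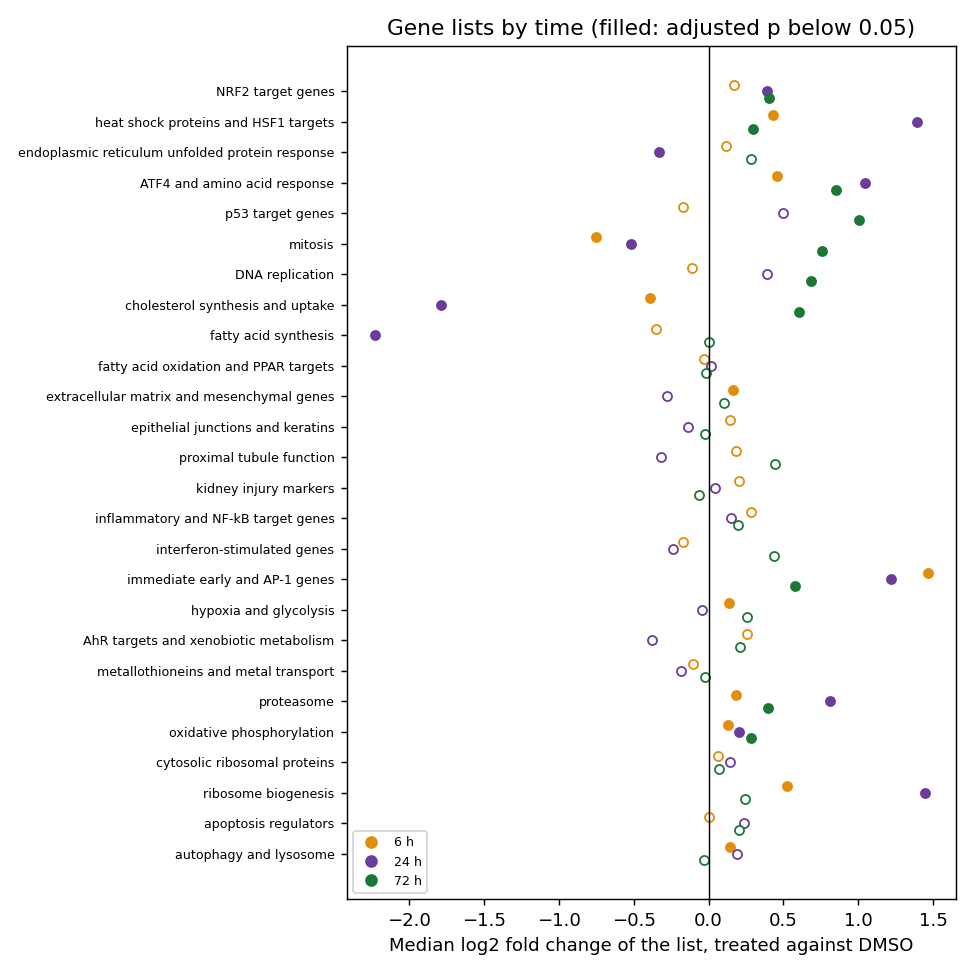
Median log2 change of each tested gene list (x axis, chlorothalonil against DMSO) by list (y axis) and time (colour), with filled points for lists with an adjusted p below 0.05 by camera (n = 3 arrays per group). The lowest called medians are those of fatty acid synthesis (−2.23) and cholesterol synthesis and uptake (−1.79) at 24 h, and the called medians above 0 fall below 0 when scaled to the poly-A controls over all arrays except AP-1 at 6 and 24 h, heat shock and ribosome biogenesis at 24 h, and ATF4, p53, mitosis and DNA replication at 72 h.

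At 72 h the stress genes were still higher, and mitosis genes, lower at the earlier times, were now higher than in DMSO, as were those of DNA replication. No call of these lists was kept with an estimated correlation (adjusted p = 0.470 for ATF4 and mitosis, 0.5003 for DNA replication and 0.127 for p53 targets). Ifi27l2b, an interferon-inducible gene, stood at log2 12.60 ± 0.067 against 5.03 ± 0.39 (mean ± SD, n = 3), 190.2-fold higher, and Hmox1 was at least 32.9-fold and Atf3 at least 45.5-fold higher. Aqp1, the water channel of the proximal tubule, stayed at background in treated arrays, at least 8.23-fold lower than in DMSO, which had gone from log2 2.14 at 24 h to 7.04.

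In mitosis 28 of 30 genes rose and 0 fell. The median was 0.76 and 0.085 poly-A scaled (adjusted p = 1.23e-07, or 0.470 estimated). Top2a rose by 0.42 (−0.26 poly-A scaled), and Mki67 had a log2 change of −0.035 (adjusted p = 0.772). In DNA replication 24 of 30 genes rose and 1 fell. The median was 0.68 and 0.012 poly-A scaled, where leaving out any 1 of 4 arrays turned it below 0, at the lowest to −0.094 without treated replicate 3 (adjusted p = 0.000161, or 0.5003 estimated). Tyms, which makes thymidylate, rose 2.24-fold, and Rfc4, Mcm6 and Prim1 of the replication machinery rose by 1.01, 0.89 and 0.80. Of the p53 target genes, 13 of 17 genes rose and 2 fell. The median was 1.01 and 0.34 poly-A scaled (adjusted p = 0.00231, or 0.127 estimated). Cdkn1a rose 2.42-fold and Mdm2 2.79-fold, and Ccng1 rose by 0.62 (−0.049 poly-A scaled).

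Of the ATF4 and amino acid response genes, 23 of 27 genes rose and 3 fell. The median was 0.85 and 0.18 poly-A scaled (adjusted p = 1.79e-06, or 0.470 estimated). Trib3 rose 17.2-fold, Asns, asparagine synthetase, 4.98-fold, Chac1, which degrades glutathione, 4.79-fold and Ddit3 2.82-fold. Of the NRF2 target genes, 18 of 27 genes rose and 2 fell. The median was 0.41, turned to −0.27 poly-A scaled (adjusted p = 0.00388, or 0.474 estimated). Nqo1, lower at 6 h, rose by 0.74, Srxn1 by 1.69 and Gclm by 0.95, and Txnrd1 by 0.43 (−0.24 poly-A scaled). Slc7a11 was at background in both groups, where it passed the test with a log2 difference of 0.38 (−0.29 poly-A scaled). The call of Slc7a11 at 72 h was lost without replicate 1 or 2 of either group (adjusted p = 0.0537 to 0.107).

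Of the heat shock proteins and HSF1 targets, 11 of 20 genes rose and 2 fell. The median was 0.29, turned to −0.38 poly-A scaled (adjusted p = 0.0438, or 0.604 estimated). This call was lost without DMSO replicate 2 at 6 h, which enters the pooled spread (adjusted p = 0.0520), without DMSO replicate 3 at 72 h (0.0812), and under quantile normalization (0.0523) and poly-A scaling (0.0688). Hspa1a rose at least 2.73-fold. Of the immediate early and AP-1 genes, 17 of 30 genes rose and 3 fell. The median was 0.58, 0.52 with background genes at their bound and turned to −0.094 poly-A scaled, or 0.10 there without treated replicate 1 (adjusted p = 0.00384, or 0.5003 estimated). In the proteasome 27 of 32 genes rose and 1 fell (27 higher and 2 lower adjusted over the list alone). The median was 0.40, turned to −0.28 (adjusted p = 0.000151, or 0.470 estimated). In oxidative phosphorylation 26 of 41 genes rose and 2 fell. The median was 0.28, turned to −0.39 (adjusted p = 0.00149, or 0.635 estimated), with Ndufa5, Ndufa2 and Uqcrq of the respiratory complexes up by 1.14, 0.97 and 0.77 and Sdhb by 0.62 (−0.055 poly-A scaled). Neither call held on the poly-A scale (adjusted p = 0.108 and 0.294), where Sdhb had 0.12 without treated replicate 1. In cholesterol synthesis and uptake, lower at both earlier times, 17 of 21 genes rose and 1 fell. The median was 0.60, turned to −0.070 poly-A scaled, or 0.019 there without treated replicate 1 (adjusted p = 0.00241, or 0.470 estimated).

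Outside these lists, Ankrd1 rose at least 79.4-fold, Nppb at least 31.0-fold, Creb5 at least 18.1-fold, Sprr1a at least 7.76-fold and Stmn4, a tubulin-binding protein, at least 7.96-fold. Mgp, an inhibitor of calcification, fell by 4.89, Fam180a by 4.48, with 1 of 3 treated arrays above background, Rtn1 by 3.65, the protease Adamts10 by 3.61, the matrix protein Podn by 3.44, the protocadherin Pcdhb12 by 3.40 and glycerol kinase Gk by 3.35. Cxcl13, a B-cell chemokine, was at least 13.2-fold lower and the transcription factor Hlf at least 5.87-fold lower. Each of these lower genes had risen in DMSO since 24 h, by 0.81 (Adamts10) to 4.75 (Gk).

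Of the 38 proximal tubule genes fixed in advance, 6 were tested, and at 72 h they were split (4 higher, 2 lower of 6, adjusted p = 0.753). Beside the lower Aqp1, the peptidase Mme fell by 1.11, while Gatm, the first enzyme of creatine synthesis, rose by 2.26 and Ggt1, which cleaves glutathione outside the cell, rose at least 3.11-fold. The extracellular matrix and mesenchymal genes were split too (13 higher, 12 lower of 31, 14 and 12 adjusted over the list alone, adjusted p = 0.532), with the collagens Col3a1 and Col12a1 down by 3.24 and 3.29, Tagln up by 1.12 and Mmp10 up at least 1.62-fold. Autophagy and lysosome genes (10 higher, 10 lower of 25, adjusted p = 0.654) showed Hexa and Atg3 down by 0.60 and 0.65, Gabarapl1 up by 0.76 and Ctsd up by 0.59 (−0.084 poly-A scaled, 0.13 there without treated replicate 1).

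Not called at 72 h were also the unfolded protein response (10 higher, 6 lower of 20, adjusted p = 0.641), fatty acid synthesis (3 higher, 1 lower of 14, adjusted p = 0.988) and fatty acid oxidation with PPAR targets (8 higher, 4 lower of 17, adjusted p = 0.905). No call was made for epithelial junctions and keratins (2 higher, 4 lower of 8, adjusted p = 0.80), kidney injury markers (3 higher, 4 lower of 11, 3 and 5 adjusted over the list alone, adjusted p = 0.644), inflammatory and NF-kB target genes (4 higher, 4 lower of 17, 3 and 4 adjusted over the list alone, adjusted p = 0.976), interferon-stimulated genes (11 higher, 4 lower of 21, adjusted p = 0.241) and hypoxia and glycolysis (14 higher, 2 lower of 28, adjusted p = 0.129). The same held for AhR targets (3 higher, 4 lower of 13, adjusted p = 0.776), metallothioneins (0 higher, 4 lower of 12, 0 and 3 adjusted over the list alone, adjusted p = 0.253), cytosolic ribosomal proteins (3 higher, 1 lower of 25, 2 and 1 adjusted over the list alone, adjusted p = 0.703), ribosome biogenesis (12 higher, 2 lower of 26, 11 and 2 adjusted over the list alone, adjusted p = 0.178) and apoptosis regulators (7 higher, 3 lower of 18, adjusted p = 0.654). Mt1 was at background in both groups.

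Median, mean and test differed in sign for 8 of the uncalled lists at 72 h. The test pointed down although the median was above 0 for fatty acid synthesis (median 0.0054, mean 0.12), extracellular matrix (0.10, −0.11) and inflammatory genes (0.20, 0.30). It pointed down with a mean above 0 for epithelial junctions (−0.025, 0.048), kidney injury markers (−0.062, 0.24) and autophagy (−0.029, 0.034). It pointed up for fatty acid oxidation (−0.019, 0.091) and proximal tubule function (0.45, −0.031).

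Markers of other cell types were near background with exceptions, and their lists were too small to test. Cd68, a lysosomal protein of macrophages and other cells, rose 46.7-fold at 72 h, to log2 9.45 ± 0.20 (n = 3), against a level above background in 2 of 3 DMSO arrays. It rose at least 2.04-fold at 24 h, and at 6 h it stood at 3.83 ± 0.46 with DMSO at background (adjusted p = 0.000519). Itgax, an integrin of dendritic cells and outside that list, rose at least 17.7-fold at 72 h. Of 17 leukocyte markers the other tested one, Cd14, had changes of 0.086, 0.37 and 0.022, the middle one called and −0.70 poly-A scaled. Of 13 fibroblast markers 3 were tested, and Des rose by 1.21 and 1.98 at 6 and 24 h and at least 10.4-fold at 72 h, Mfap5 changed by 0.36, −0.21 and −0.48 (−0.25 at 6 h on the poly-A scale) and Fbln1 by 0.17 at 6 h (adjusted p = 0.488). Of 14 endothelial markers Ramp2 rose by 0.79 and Egfl7 by 1.20 at 6 h. Tek was at background in both groups at 6 h and fell by 1.66 at 72 h (log2 3.84 ± 0.33 against 5.51 ± 0.19, n = 3), with 1 of 3 treated arrays above background. Of 10 podocyte markers, Cd2ap and Synpo fell by 0.56 and 0.43 at 72 h and Wt1 rose by 0.43 (−0.24 poly-A scaled). The call of Synpo at 72 h was lost without any 1 array of that time except treated replicate 2 (adjusted p = 0.0738 to 0.137), and that of Wt1 at 72 h without replicate 1 or 2 of either group (0.0703 to 0.139). None of 20 distal nephron markers passed the filter (0 tested).

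At 72 h limma called 5881 of 9149 genes (64.3%), 3408 higher and 2473 lower, with 703 and 415 changed at least 2-fold. Poly-A scaling called 3776, 8.26% of them higher (2153 and 14.6% without treated replicate 1, 2508 and 10.2% without DMSO replicate 2). None of the 10 list calls was kept with an estimated correlation (0).

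Across the 3 times, 8351 genes (91.3%) were called by the F test, 926 were higher at all 3 times and 677 lower at all 3, where independent lists would give 370 and 244. Atf3, Hmox1, Ddit3, Mdm2 and Cdkn1a were among the genes higher at each time. The 6 and 24 h effects were shared in the same direction for 2781 genes (1442 higher at both with 994 expected, 1339 lower with 903 expected) and opposite for 1207 (1926 expected). For 24 and 72 h these numbers were 3319 (1986 with 1332 expected, 1333 with 768 expected) and 1059 (2025 expected), and for 6 and 72 h 2399 (1295 with 948 expected, 1104 with 786 expected) and 1219 (1771 expected). The times share no arrays, and the changes were correlated across genes, which are not independent replicates, at 0.373, 0.446 and 0.241.

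**Figure D3:**
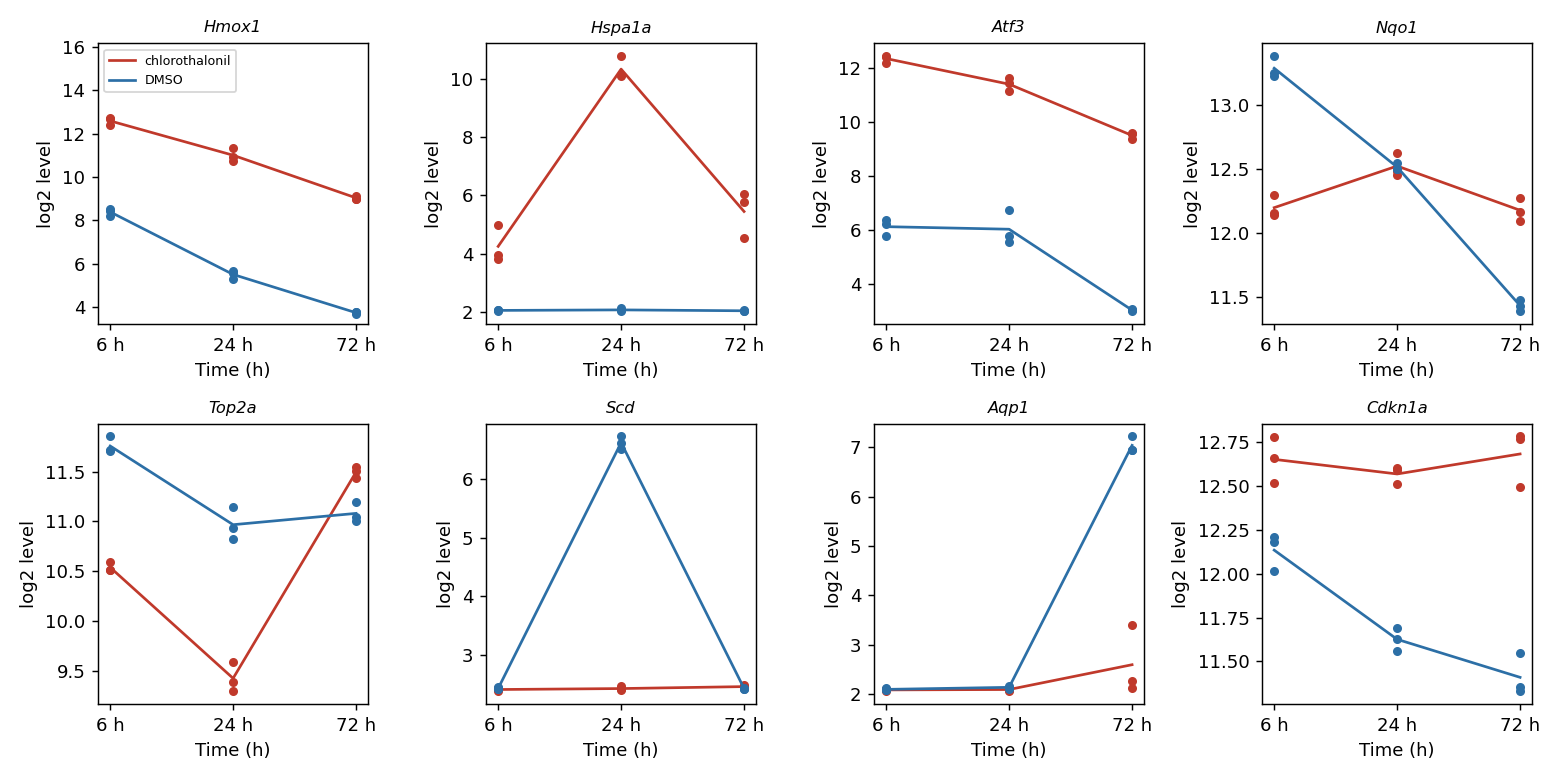
Log2 level (y axis) of 8 genes in each array at 6, 24 and 72 h (x axis), with chlorothalonil in red, DMSO in blue and lines through the means of 3 arrays. Hmox1 and Atf3 are higher in every treated array at every time, Hspa1a peaks at 24 h at 10.32, and Nqo1 moves from −1.09 at 6 h to 0.74 at 72 h, whereas the rises of Cdkn1a at 6 and 24 h and of Top2a at 72 h turn below 0 when scaled to the poly-A controls (Cdkn1a at 24 h not without DMSO replicate 1).

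The effect of chlorothalonil differed between times by direct tests. Hspa1a had an effect 6.05 ± 0.47 (SE) larger at 24 h than at 6 h and 4.84 smaller at 72 h than at 24 h. These are fitted log2 differences, which for a gene at background in a group depend on its background value. Cdkn3, a phosphatase of dividing cells, had an effect 4.56 ± 0.10 larger at 72 h than at 24 h. Beside each list below, the first adjusted p is with the preset and the second with an estimated correlation.

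From 6 to 24 h, 5761 genes had a different effect, 3623 more positive and 2138 more negative. Poly-A scaling called 1491, 17.4% more positive against 62.9% here, with 2635 and 55.4% without DMSO replicate 1 at 24 h and 2422 and 6.94% without replicate 3. Sprr1a, Nppb, Plcd4 and the metalloprotease Mmp12 gained 6.96, 5.99, 5.11 and 4.97, and Col8a2, Tmem176b, Mgp, Tm7sf2 and Ropn1l shifted by −5.87, −5.52, −5.48, −4.88 and −4.75. The lists that became more positive were the heat shock genes (median difference 0.68, adjusted p = 0.00851 and 0.486), the proteasome (0.66, adjusted p = 2.23e-06 and 0.279) and ribosome biogenesis (0.91, adjusted p = 2.35e-06 and 0.190). More negative were fatty acid synthesis (−1.39, adjusted p = 1.39e-08 and 0.00870) and cholesterol synthesis (−1.26, adjusted p = 3.82e-10 and 0.0560). The unfolded protein response did so too (−0.60, adjusted p = 0.000147 and 0.225), with extracellular matrix (−0.54, adjusted p = 0.00101 and 0.387). Hypoxia and glycolysis followed (−0.27, adjusted p = 0.00254 and 0.555), with AP-1 (−0.20, adjusted p = 0.0325 and 0.613) and AhR targets (−0.46, adjusted p = 0.0424 and 0.353). The larger change lay in DMSO for heat shock (median −0.71 against −0.062 in treated arrays), ribosome biogenesis (−1.5 against −0.59), cholesterol (1.83 against 0.36), fatty acid synthesis (2.06 against 0.40) and AhR targets (1.15 against 0.28). DMSO and treated arrays moved apart in the proteasome (−0.38 and 0.27) and the unfolded protein response (0.31 and −0.23). Without DMSO replicate 3 at 24 h the proteasome difference was −0.056 on the poly-A scale.

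From 24 to 72 h, 5274 genes differed, 2551 more positive and 2723 more negative. Poly-A scaling called 1469, 85.3% more positive against 48.4% here, with 2181 and 51.6% without DMSO replicate 1 at 24 h and 2707 and 93.4% without replicate 3. Ropn1l, Pimreg, Aldoc and Rnf157 gained 6.23, 5.56, 5.30 and 5.12, and Hist4h4, Sdcbp2, Ppfibp2 and Ccl2 shifted by −5.89, −5.19, −4.98 and −4.89. Mitosis became more positive (median difference 1.38, adjusted p = 5.92e-14 and 0.225). Cholesterol (2.59, adjusted p = 9.00e-14 and 0.0235) and fatty acid synthesis (2.35, adjusted p = 3.15e-09 and 0.00870) became more positive too. So did the unfolded protein response (0.40, adjusted p = 0.00361 and 0.353), p53 targets (0.31, adjusted p = 0.0276 and 0.225) and hypoxia and glycolysis (0.41, adjusted p = 0.00560 and 0.593). Heat shock genes (−1.20, adjusted p = 1.45e-05 and 0.225) and ribosome biogenesis (−1.10, adjusted p = 1.40e-09 and 0.0584) became more negative. The proteasome (−0.42, adjusted p = 1.37e-05 and 0.325) and AP-1 (−0.70, adjusted p = 0.0127 and 0.570) did likewise. Lipid synthesis changed mostly in DMSO, by −3.02 for cholesterol and −1.77 for fatty acid synthesis against −0.44 and 0.017 in treated arrays, as did the unfolded protein response (−0.49 against −0.032). Mitosis (1.11 against −0.29 in DMSO), heat shock (−0.93 against 0.043), ribosome biogenesis (−0.83 against 0.19) and AP-1 (−0.65 against −0.031) changed mostly in treated arrays. On the poly-A scale leaving out any 1 of 6 arrays turned the proteasome difference above 0, to at most 0.26 without DMSO replicate 3 at 24 h, which also turned AP-1 (0.034).

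From 6 to 72 h, 5396 genes differed, 3420 more positive and 1976 more negative. Poly-A scaling called 1139, 55.4% more positive against 63.4% here. Ifi27l2b, Nppb, Stmn4, the cell cycle gene Depdc1b and Mmp12 gained 6.79, 4.98, 4.55, 4.49 and 4.47, and Mgp, Gpr15lg, Cxcl13, Aoc3 and 1700109H08Rikl shifted by −7.52, −5.82, −5.54, −5.49 and −5.34. More positive were mitosis (median difference 1.52, adjusted p = 1.19e-12 and 0.240) and cholesterol synthesis (1.02, adjusted p = 2.73e-05 and 0.225). DNA replication (0.73, adjusted p = 0.000759 and 0.555) and p53 targets (0.79, adjusted p = 0.000453 and 0.0560) were more positive as well. More negative were AP-1 (−0.35, adjusted p = 5.04e-05 and 0.325), extracellular matrix (−0.11, adjusted p = 0.0276 and 0.597) and autophagy (−0.17, adjusted p = 0.0435 and 0.492).

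**Figure D4:**
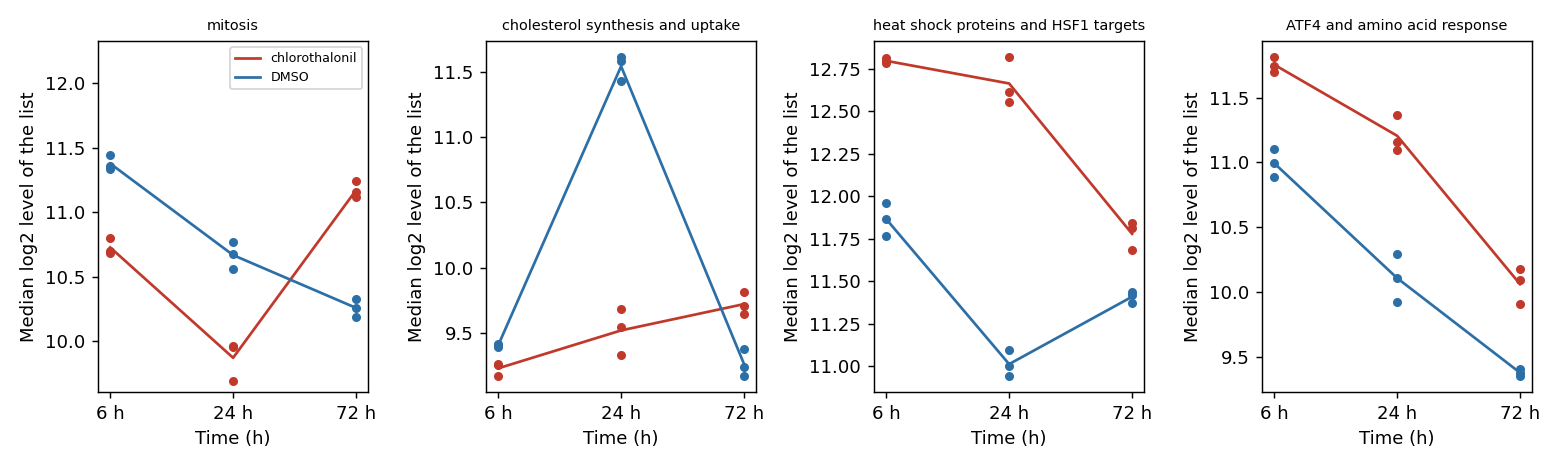
Median log2 level of 4 gene lists (y axis) in each array at 6, 24 and 72 h (x axis), with chlorothalonil in red, DMSO in blue and lines through the means of 3 arrays. Cholesterol genes lie at 9.48 in treated and 11.5 in DMSO arrays at 24 h, and mitosis genes lie below DMSO at 6 and 24 h and above it at 72 h. When scaled to the poly-A controls over all arrays the treated minus DMSO medians turn below 0 for heat shock at 6 and 72 h, for ATF4 at 6 and 24 h and for cholesterol at 72 h.

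In DMSO alone, as many genes differed by time as by treatment, but time may include array batch. From 6 to 24 h DNA replication, mitosis and ribosome biogenesis genes fell while lipid synthesis and interferon genes rose. From 24 to 72 h lipid synthesis and hypoxia genes fell. With an estimated correlation the calls of fatty acid synthesis (adjusted p = 0.0122 and 0.00634) and the fall of cholesterol genes (0.00893) were kept, and those of DNA replication (0.286), mitosis (0.486), ribosome biogenesis (0.0560), the rise of cholesterol genes (0.0584), interferon (0.225) and hypoxia genes (0.202) were not. The actin 3′ minus 5′ signal moved with time too, at log2 1.0 ± 0.11, 1.27 ± 0.046 and 1.68 ± 0.29 in DMSO and 0.91 ± 0.030, 1.11 ± 0.066 and 1.75 ± 0.077 in treated arrays at 6, 24 and 72 h (mean ± SD, n = 3). Tm7sf2 went from background at 6 h (log2 3.36 ± 0.42, n = 3) to 11.49 ± 0.10 at 24 h, at least 179.6-fold, and Nppb went the other way, from 10.18 ± 0.16 to background, at least 72.3-fold lower. Mvd of cholesterol synthesis fell 31.3-fold between 24 and 72 h.

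From 6 to 24 h, 6673 genes changed in DMSO, 3010 higher and 3663 lower (45.1% higher, and 34.7% with each array centred on its median, which moved the median log2 change from −0.054 to −0.22). Poly-A scaling called 3033, 63.2% higher, and without DMSO replicate 1 at 24 h 4665 and 30.3%. Dhrs3, Olfml2a and Zc3h6 rose at least 35.2-fold, at least 15.7-fold and at least 28.8-fold, and Them7 rose by 5.92, with 1 of 3 arrays at 6 h above background. Plcd4, Etv5 and Mylk3 were at least 14.3-fold, at least 12.8-fold and at least 10.3-fold lower, and Lcp1 fell by 4.67, with 1 of 3 arrays at 24 h above background. Cholesterol synthesis rose (median 1.83, adjusted p = 2.04e-09 and 0.0584), as did fatty acid synthesis (2.06, adjusted p = 3.87e-07 and 0.0122). Interferon-stimulated genes (1.59, adjusted p = 8.93e-06 and 0.225), AhR targets (1.15, adjusted p = 0.0143 and 0.273) and fatty acid oxidation (0.35, adjusted p = 0.00336 and 0.353) rose too. DNA replication fell (median −1.37, adjusted p = 2.26e-08 and 0.286), with mitosis (−0.81, adjusted p = 2.48e-06 and 0.486). Ribosome biogenesis (−1.5, adjusted p = 5.18e-10 and 0.0560) and ATF4 (−1.18, adjusted p = 0.000453 and 0.555) fell as well. Heat shock (−0.71, adjusted p = 0.00178 and 0.383) and the proteasome (−0.38, adjusted p = 0.00121 and 0.486, with a median of 0.079 on the poly-A scale without DMSO replicate 3 at 24 h) did so too.

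From 24 to 72 h, 5550 genes changed in DMSO, 3324 higher and 2226 lower (59.9% higher). Poly-A scaling called 1393, 32.7% higher, with 3062 and 77.5% without DMSO replicate 1 at 24 h and 2200 and 12.2% without replicate 3, and 909 and 35.5% without DMSO replicate 3 at 72 h. Loxl1 and Serping1 rose at least 16.2-fold and at least 9.51-fold, Pmp22, above background in 2 of 3 arrays at 24 h, by 5.51, Ptn by 5.23, and C19h16orf74 by 5.06, with 1 of 3 arrays at 24 h above background. Poteml2 was at least 45.5-fold lower, and Ropn1l, Car3 and Aldoc fell by 5.12, 4.91 and 4.84, Aldoc to a level above background in 1 of 3 arrays. Cholesterol synthesis fell (median −3.02, adjusted p = 6.32e-19 and 0.00893), with fatty acid synthesis (−1.77, adjusted p = 3.90e-11 and 0.00634). Hypoxia and glycolysis (−1.06, adjusted p = 3.06e-10 and 0.202) and ATF4 (−1.05, adjusted p = 1.95e-10 and 0.225) fell. The proteasome (−0.41, adjusted p = 1.26e-08 and 0.225) and the unfolded protein response (−0.49, adjusted p = 1.37e-05 and 0.195) fell. Mitosis (−0.29, adjusted p = 0.00164 and 0.622) and NRF2 targets (−0.34, adjusted p = 0.00178 and 0.360) fell, and proximal tubule function (−1.10, adjusted p = 0.0147 and 0.268) and DNA replication (−0.13, adjusted p = 0.0203 and 0.703) did too. Extracellular matrix genes rose (median 0.31, adjusted p = 0.0361 and 0.599). On the poly-A scale the last median was −0.073 and −0.17 without DMSO replicate 2 and 3 at 24 h, and that of DNA replication 0.0081 without replicate 1.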

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

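The comparison of the 5S ribosomal RNA probe set was chosen only after its values had been seen. Results are given here because a test of the difference between times passed, for single genes and lists together with calls in opposite directions at the times compared, or because probe sets outside the gene-level tests carried a signal.

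The effect of chlorothalonil differed between 6 and 24 h for 5761 genes, between 24 and 72 h for 5274 and between 6 and 72 h for 5396, each by the test of the difference itself. Of 100 splits of treatment within time, only the real one called as many genes for each of these differences. The same held for the F test over the 3 times (8351 genes). The highest other splits called 4255, 4384, 3318 and 6164 genes. These were among the 19, 19, 19 and 30 of 99 other splits that kept the real grouping at 1 time or more. The remaining splits put real differences into the spread and called at most 1, 0, 0 and 0. This ranking cannot exclude chance for the 4 counts. For a comparison of 3 arrays with 3, the 10 splits are too few for a share under 0.05. Only 1 of 10, the real one, reached its count, with 5451 genes at 6 h (highest other split 1), 6418 at 24 h (0) and 5881 at 72 h (4), and with 6673 between 6 and 24 h (0) and 5550 between 24 and 72 h (0) in DMSO.

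The genes of mitosis and of cholesterol synthesis and uptake were lower than DMSO early and higher at 72 h, by calls that were not kept with an estimated correlation (adjusted p = 0.470, 0.5003 and 0.470 for mitosis and 0.470, 0.0898 and 0.470 for cholesterol at 6, 24 and 72 h). The median of mitosis went from −0.75 at 6 h and −0.52 at 24 h to 0.76 at 72 h, with median differences of 1.52 and 1.38 (adjusted p = 0.240 and 0.225 with an estimated correlation). That of cholesterol synthesis went from −0.39 and −1.79 to 0.60, with differences of 1.02 and 2.59 (0.225 and 0.0235), the rise after 24 h coming with a fall of 3.02 in DMSO. On the poly-A scale the 4 differences stayed above 0 (1.46, 1.79, 0.96 and 2.99), but the cholesterol median at 72 h was −0.070 (0.019 without treated replicate 1).

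Of 186 named genes, 43 were called in opposite directions at the times of 1 or more pairs, with the difference called too, 69 times in all. Values are the later minus the earlier log2 effect, fitted on the deposited scale. From 6 to 24 h the matrix genes Col8a2, Mgp, Col3a1 and Mfap5 shifted by −5.87, −5.48, −2.01 and −0.57, the metabolic genes Ephx1, Eci1, Gstm2, Hexa and Gclm by −2.64, −2.36, −2.17, −0.77 and 1.13, and Tmem176b, Cxcl13, F11r, Cdkn3 and Zc3h6 by −5.52, −2.17, −1.04, −2.41 and −2.58.

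From 24 to 72 h the division genes Pimreg, Cenpf, Top2a, Bub1b, Racgap1, Tyms and Cdkn3 shifted by 5.56, 2.64, 1.96, 1.38, 1.03, 1.48 and 4.56. The lipid genes Acat2, Ebp, Dhcr7, Mvd, Fads1 and Acss2 shifted by 2.87, 2.76, 3.77, 4.07, 3.24 and 3.94. Ephx1, Eci1, Gatm, Gk, Aldoc and Aoc3 had 3.18, 1.56, 2.85, −4.35, 5.30 and −2.26, and Xbp1, Stat2, Psmb9, Fos, Atg3 and Ccng1 had 1.29, 1.71, 1.78, −1.20, −1.33 and 0.90. Ropn1l, Rnf157, Zc3h6, Ppfibp2 and Pmp22 had 6.23, 5.12, 4.46, −4.98 and −3.18.

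From 6 to 72 h the division genes Pimreg, Cenpf, Top2a, Bub1b, Racgap1 and Depdc1b shifted by 2.37, 1.82, 1.64, 1.72, 1.5 and 4.49, and the lipid genes Acat2, Dhcr7, Mvd and Fads1 by 1.40, 2.06, 2.24 and 0.67. The matrix genes Col8a2, Mgp, Col3a1 and Mfap5 had −2.40, −7.52, −3.71 and −0.84, and Nqo1, Gclm, Gstm2, Hexa and Aoc3 had 1.83, 1.30, −0.71, −1.06 and −5.49. Tmem176b, Cxcl13, F11r, Stat2, Fos and Birc2 had −3.32, −5.54, −0.37, 1.57, −4.49 and 0.89. Of the 69, 4 rest on a time at which all arrays of both groups lay at background and show no turn, those of Cxcl13 (at 6 h), Aoc3 from 24 to 72 h (at 24 h) and Ppfibp2 (at 72 h).

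A control probe set for 5S ribosomal RNA, which no gene-level test used, was brighter in the treated arrays by 3.86 at 6 h, 5.66 at 24 h and 3.90 at 72 h on the log2 scale (exact permutation p = 0.00025 over the 3 times, n = 3 per group, the smallest that 8000 permutations allow), and by 3.25, 4.59 and 3.23 on the poly-A scale. Of 3646 probe sets without a gene symbol, the same model called 2016 at 6 h (669 higher), 2184 at 24 h (659 higher) and 2068 at 72 h (541 higher) on the deposited scale.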

How the results depend on the processing

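Scaling to the poly-A controls, also without single arrays, and list medians with background genes at their bound were chosen only after the data had been seen, and the other alternatives before. Counts of genes and lists stayed within 1.5 times under array weights (9 of 9), centring (12 of 12), a filter at log2 6 (12 of 12), no filter (12 of 12), an intensity trend with robust spread (9 of 9), only the 6 arrays of a time (3 of 3) and quantile normalization (11 of 12, with 7 lists at 6 h in place of 11). Testing all probe sets on their own called 9027, 10697 and 9824 at 6, 24 and 72 h, 14502 at any time, 9116 (24 h against 6 h), 8457 (72 h against 24 h) and 8997 (72 h against 6 h) for the differences, and 10904 and 10191 in DMSO, since more features were tested. A change of at least 2-fold left 1050, 1709 and 1118, 2944 at any time, 1931, 1693 and 1775 for the differences, and 2107 and 1048 in DMSO, with 335, 411 and 158 shared by 6 and 24 h, 24 and 72 h, and 6 and 72 h. Camera with an estimated correlation called 0, 1 and 0 lists at the 3 times, and fry 24, 22 and 22.

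Without 1 array the counts of genes were 4963 to 5122 at 6 h, 6039 to 6208 at 24 h, 5429 to 5583 at 72 h, 8252 to 8381 at any time, 5472 to 5716, 4994 to 5146 and 5068 to 5317 for the differences, and 6326 to 6574 and 4969 to 5274 in DMSO. The lists called were 7 to 13 (7 without DMSO replicate 2 at 6 h), 11 to 12 and 9 to 10. Of 1698 named-gene values without 1 array, 1675 kept side of the threshold, 21 lost the call and 2 gained it. With a call in either fit (as below), 0 changed sign. Quantile normalization and centring each gave 250, 2, 1 and 0 of 253.

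Centring moved the share of higher calls in DMSO from 6 to 24 h from 45.1% to 34.7%, and poly-A scaling moved 46.7%, 55.7% and 57.9% higher at 6, 24 and 72 h to 6.07%, 3.93% and 8.26%. That scaling called 3776 genes at 72 h, 1491, 1469 and 1139 for the differences, and 3033 and 1393 in DMSO, and kept 3133, 3099 and 2785 calls at the 3 times in the same direction. Without DMSO replicate 1 at 24 h it called 2635 (24 h against 6 h) and 2181 (72 h against 24 h) for the differences and 3062 in DMSO from 24 to 72 h, and of 124 values of named genes 112 stayed, 6 lost the call and 6 changed sign (Abcg2 −0.24, Rpl18 −0.36, Rpl27 −0.47, Rps24 −0.49, Cd14 −0.28 and Nqo1 −0.67 at 24 h). Scaling to the controls adds their spread to every gene, and which scale is nearer to the cells was not tested. Of 253 values of named genes 195 stayed, 36 lost the call, 1 gained it and 21 changed sign: at 6 h Clu −0.070, Mfap5 −0.25, Txnrd1 −0.048 and Cdkn1a −0.10, at 24 h Krt8 −0.27, Abcg2 −0.55, Psmd14 −0.15, Rpl18 −0.77, Rpl27 −0.89, Rps24 −0.90, Cd14 −0.70, Nqo1 −1.07, Gclm −0.29 and Cdkn1a −0.13, and at 72 h Sdhb −0.055, Ctsd −0.084, Wt1 −0.24, Txnrd1 −0.24, Slc7a11 −0.29, Ccng1 −0.049 and Top2a −0.26. The second brightest probe set turned Mtf1 at 24 h to −0.55 and Slc11a2 at 24 h to 0.31, with 47 of 52 the same and 3 calls lost, and the cause was not tested.

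Of lists not called, centring added ribosomal proteins at 24 h, no filter added the unfolded protein response and fatty acid synthesis at 6 h and DNA replication and ribosomal proteins at 24 h. Poly-A scaling added NRF2 and inflammatory genes at 6 h, inflammatory genes at 24 h and interferon genes at 72 h. The cause was not tested.

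The replicate numbers share only a number. Deviations from the group mean of the treated and the DMSO array of 1 number and time correlated at −0.0438 to 0.305 over 9 pairs, with 3 over 0.1, and 4 of 9 treated arrays correlated best with their own number. With the replicate number as a block within time 5428, 6409 and 5888 genes were called, of which 5252, 6247 and 5678 were called in the same direction without it. Of 253 values of named genes 4 lost the call, and NRF2 at 24 h had an adjusted p = 0.0513. With the block across times the numbers were 5376, 6348 and 5817. Signal over background sets the limit for dim genes: at or below log2 4 on every array of a group a change is only a bound.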

Other observations

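The zinc finger comparison, the tests on control transcripts, the 24 h test of probe noise and the test on probe sets of 1 gene were chosen only after their results had been seen. Genes of zinc finger proteins, many of them transcription factors, were lower at 6 h more often than other genes. Of 219 tested genes whose symbols start with Zfp, Znf, Zkscan, Zscan or Zbtb, 124 were lower and 26 higher at 6 h (56.6% lower against 31.2% of other genes). The odds ratio was 2.88 (95% interval 2.18 to 3.82, Fisher p = 1.78e-14, with genes not independent of each other). At 72 h 93 were lower and 29 higher (42.5% against 26.7%, odds ratio 2.03, 1.53 to 2.69, Fisher p = 6.44e-07), and at 24 h 79 and 53 (36.1% against 31.0%, odds ratio 1.26, 0.939 to 1.68, Fisher p = 0.120). The median log2 change (−0.48, −0.15 and −0.27 at 6, 24 and 72 h) was below that of other genes also under quantile normalization, centring and poly-A scaling (−1.10, −1.22 and −0.94 against −0.62, −1.01 and −0.59).

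The treatment effect at 24 h ran against the change between times in DMSO. Its correlation across genes, which are not independent, with DMSO at 72 h minus 6 h was −0.587 over 9149 genes, and −0.584 after removing the medians of 20 bins of mean level. The first shares no array, which argues against shared control arrays as the whole source (pairs with shared arrays gave −0.678 and −0.526), and the second argues against a bias with intensity. Of 7156 genes called between DMSO at 72 h and 6 h, 78.5% lay in the treated arrays at 24 h on the 6 h side of DMSO at 24 h, which restates that sign and is no test of the hypothesis of a delayed culture-time change. The effects at 6 and 72 h gave −0.162 and −0.259 with the DMSO change that shares no array with them, and whether a delay, or a separate effect on genes that also change with time, lay behind this was not tested.

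The 24 probe sets of poly-A control transcripts were brighter in treated arrays by 0.79 (95% interval 0.50 to 1.12, exact permutation p = 0.00025, the smallest possible, n = 3 per group), with log2 means of 10.60 against 9.98, 10.86 against 9.79 and 10.68 against 10.01 at 6, 24 and 72 h. A single deviating array is argued against, since with any 1 array left out the difference was at least 0.65 (without DMSO replicate 1 at 24 h), with an exact permutation p of at most 0.0005. The 18 probe sets of hybridization controls differed by 0.29 (−0.050 to 0.67, exact permutation p = 0.111, n = 3 per group), with an upper end below the poly-A difference. Yet the difference between the 2 kinds of control was 0.50 (−0.0034 to 0.98, exact permutation p = 0.0535, n = 3 per group), an interval that includes 0, so a difference in hybridization or scanning cannot be told apart. Less messenger RNA per total RNA in treated cells might also give the 0.79 and stays open, since the amounts of control transcript added are not given in the sources used here.

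At 6 h, 88 genes at background in all DMSO arrays were called higher in treated arrays with a fitted rise of at least 2-fold from values below background, among them Ccl2, Ccl7, Fosb and Gpr15lg. Set against log2 4, 41 of them rose at least 2-fold, and 5 had a treated mean at or below it. By the fitted rise 29 and 14 of the 88 did so at 24 and 72 h too, when 104 and 91 genes did. Other splits of the 6 arrays gave no such gene (highest 0), but mixed splits put real differences into the spread. At 24 h, in other arrays, 42 of the 88 (47.7%) had all treated arrays above all DMSO arrays (5% by chance), against 57 of 258 other tested genes at background in DMSO at 6 h (22.1%, odds ratio 3.21, 95% interval 1.86 to 5.53), which argues against probe noise as the whole source, though noise stays open for single genes. At 72 h the shares were 33.0% and 34.9% (odds ratio 0.918, 0.528 to 1.57). Of 87 with a position in assembly GRCr8, 64 (73.6%) lay next, among arrayed genes, to one expressed above log2 8. Of 5294 other background genes 3302 did (62.4%, odds ratio 1.68, 95% interval 1.02 to 2.84, Fisher p = 0.0338). Whether transcription ran on from a neighbour stays open, as its strand and side were not used. The interval comes close to 1, the other genes include those at background in every group, and gene density was not tested. Induction of each gene by its own promoter stays open.

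Of 2600 genes with more than 1 tested probe set, 62, 129 and 268 had their 2 brightest probe sets called in opposite directions at 6, 24 and 72 h, and 792, 1111 and 784 in the same direction. As a hypothesis, transcript forms that shift with culture time may be held back under treatment. Over the 268 genes the difference between probe sets in the effect at 72 h was correlated at −0.278 (95% bootstrap interval −0.393 to −0.158, 10000 resamples) with that of DMSO at 24 h minus 6 h, which shares no array. It was −0.126 over the other 2332 genes, but the same comparison of the brightest probe sets over all 9149 genes gave −0.259, inside that interval. Such a shift and the general opposition of both comparisons cannot be told apart, and probes that bind other transcripts were not tested.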
